A study of Triticum aestivum and Secale cereale and Aegilops tauschii with 12 samples.

How the data were processed

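Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 12 libraries from 3 cereals. Rye (Secale cereale, cultivar Weining) and Aegilops tauschii (accession AL8-78, a relative of the donor of the wheat D subgenome) were sampled as seedlings of 9 days, and bread wheat (Triticum aestivum, Chinese Spring) as root and panicle. The rye libraries targeted H3K4me3, H3K9ac, H3K9me2 and H3K27me3, the Ae. tauschii libraries H3K4me3, H3K9ac and H3K27me3, the wheat root libraries H3K4me3, H3K9ac and H3K27me3, and the wheat panicle libraries H3K4me3 and H3K27me3. Each combination of species, tissue and mark had 1 library. The 3 wheat root libraries were grouped by their titles and library names, which say root, whereas their source and tissue fields say panicle, and the extraction protocol of all wheat libraries describes seedlings. Which of these labels holds could not be settled from the peak lists, so every statement on root and panicle depends on the titles.

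The authors deposited 1 peak list per library and no read counts per region. Per the submitters' processing notes the tools were fastp 0.22.0, BWA 0.7.17-r1188 and MACS2 2.1.0.20150731. Per the file headers, the rye and Ae. tauschii lists came from MACS2 in narrow mode at a q value threshold of 0.05, with a fixed extension of 200 bp, no fragment model, no local background and no control library, and with at most 1 tag kept per position and strand. The Ae. tauschii calls pooled 2 alignment files per mark and the rye calls used 1. The input names of rye, but not of Ae. tauschii, carry a tag for the removal of multiply mapped reads. Without a control or a local background, copy number and mappability enter these peak calls directly. Each deposited MACS2 table gives a pileup, a signal in stacked tags that is not scaled to depth and stops at 400. It gives a deposited fold enrichment, a ratio of the pileup to the genome-wide expectation, and deposited p and q values on the -log10 scale (neg_log10_p). The deposited peak width is in bp. The summit column of the 4 rye lists holds negative positions for 2835 to 6864 peaks, so summits were not used. The 5 wheat lists are files of 5 columns without a header, in which the authors deposited a score per peak that starts at about 50 and has many ties at 3100. What this score measures, the depth, the command line, any control library, the threshold and the genome build are not stated for wheat. The genome build is not stated for rye or Ae. tauschii either.

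Depth after duplicate removal was 33.8 to 44.1 M (1e6) tags in rye, or 4.36 to 5.70 tags per kb of the genome size given to the caller. It was 99.0 to 139 M tags in Ae. tauschii, or 23.4 to 32.9 tags per kb. Numbers of peaks and covered lengths move with depth and caller settings, so they were described and not tested between libraries. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.

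Peak starts of the wheat lists were raised by 1 bp to give 1-based coordinates. The wheat lists split each chromosome into a first and a second part, and named regions are given within their part. For positions on whole chromosomes, the largest peak end on the first part was added to positions on the second. Chromosome lengths were taken as the largest peak end over all lists of a species, which gave 7253 Mb over 7 rye chromosomes, 4025 Mb over 7 Ae. tauschii chromosomes and 14063 Mb over 21 wheat chromosomes. Peaks on unplaced sequence were left out of the main comparisons and are described in the closing section.

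Overlap of 2 marks was the share of the peaks of the first list that met a peak of the second by at least 1 bp. It was compared with 100 circular shifts of one list along each chromosome by 5% to 95% of its length, with a two-sided permutation p whose smallest possible value is 0.0099, adjusted by Benjamini-Hochberg over 13 pairs. Position along chromosomes was the log2 ratio of peaks per Mb in the outer 20% of the length at each end to that in the central 20%. Subgenomes were compared as log2 ratios of peaks per Mb within the 7 homoeologous groups. Both used two-sided sign-flip permutation tests, exact for 7 chromosomes or groups (smallest p 0.0156) and with 100000 random flips for 21 chromosomes (smallest p 1e-05), adjusted over 12 and 15 tests. Chromosomes are not biological replicates: these p values describe variation between chromosomes of 1 library. Overlaps between root and panicle and ratios of peaks per Mb between rye and Ae. tauschii were compared without a test. For the position and subgenome contrasts, 11 permutation tests of the difference between single libraries, over chromosomes and chosen after the data had been seen, stand in the closing section. Named regions were chosen by a rule fixed before the data were examined, namely the 3 widest peaks of each list (on assigned chromosomes), the 3 best-scoring wheat peaks per mark and direction with no peak of the other tissue within 5 kb, and the 3 widest overlaps of H3K4me3 and H3K27me3 in rye, Ae. tauschii and wheat root. The texts give those that bear on a comparison and summarise the rest.

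The alternatives tried were the better-scoring 50% of each list, an overlap of at least 50% of the peak, merging of peaks less than 1 kb apart, peaks of at least 500 bp, equal numbers of best-scoring peaks, covered bases in place of peak numbers, outer and central 10%, a fold enrichment of at least 4, and leaving out each homoeologous group in turn. Local shifts by 100 kb to 1 Mb, removal of peaks found in all lists of a species, inclusion of unplaced sequence, and peaks per chromosome were added after the data had been seen. Shares near genes, marked genes of fixed lists and repeat content were planned only for a matching genome or annotation. The one annotation at hand (IWGSC CS RefSeq v2.1) could not be matched to the build of the wheat lists, so these were not run and no gene is named. The overlap code was tested on simulated peaks set against the wheat root H3K4me3 list. A planted overlap of 29.9% was recovered as 31.1%, and random peaks gave a ratio to shifted peaks of 0.99. The subgenome code was tested on peaks drawn at random places on the wheat chromosomes, where a planted log2 D/A ratio of -0.32 was recovered as -0.32. Random peaks were spread evenly, so neither test covers lists that cluster towards chromosome ends. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.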

Results

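Histone marks were mapped by ChIP-seq in seedlings of rye and Aegilops tauschii and in root and panicle of bread wheat, as part of a study of regulatory regions and transposable elements in cereals. H3K4me3 and H3K9ac are marks of active promoters and other accessible regulatory sequence, H3K27me3 marks chromatin repressed by Polycomb complexes, and H3K9me2 marks heterochromatin rich in repeats. The 12 libraries fell into 12 groups of 1 library, so no value has a replicate, and intervals and tests describe single libraries. In rye, H3K9me2 gave the longest list with 1154821 peaks over 521 Mb, followed by H3K4me3 with 637578 peaks (291 Mb), H3K27me3 with 357731 peaks (349 Mb) and H3K9ac with 192244 peaks (119 Mb). In Ae. tauschii, H3K27me3 gave 259544 peaks (371 Mb), H3K4me3 179776 peaks (224 Mb) and H3K9ac 158440 peaks (154 Mb). In wheat root, H3K4me3 gave 140975 peaks (228 Mb), H3K27me3 123439 peaks (200.02 Mb) and H3K9ac 73273 peaks (60.3 Mb). In wheat panicle, H3K4me3 gave 123186 peaks (158 Mb) but H3K27me3 gave 11349 peaks (12.2 Mb). The libraries called root carry titles that say root and a tissue field that says panicle.

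Depth differed between the species. Tags kept, in units of 1e6 (M), were 36.6 M for rye H3K4me3, 33.8 M for H3K9ac, 42.7 M for H3K9me2 and 44.1 M for H3K27me3. They were 126 M for Ae. tauschii H3K4me3, 99.0 M for H3K9ac and 139 M for H3K27me3. The depth of the wheat libraries is unknown. Peaks were narrow in rye, with a median width of 335 bp for H3K4me3 and 492 bp for H3K27me3. In Ae. tauschii the median widths were 637 bp and 586 bp, and in wheat root 1539 bp and 1229 bp. The widest peaks belonged to H3K27me3 in all 4 tissues: 57537 bp on chromosome 7D of Ae. tauschii (17366352 to 17423888), 36105 bp on chromosome 4 of rye (871718875 to 871754979), 25303 bp on the first part of 6A in wheat root (3346371 to 3371673), and 15772 bp on the second part of 7D in wheat panicle (171522483 to 171538254).

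The first comparison asked how far the marks shared sites within a tissue. The active marks coincided most: 90.3% of the H3K9ac peaks of wheat root lay on H3K4me3 peaks (95% interval 90.0 to 90.5%), as did 77.5% in Ae. tauschii (77.3 to 77.7%) and 58.2% in rye (58.0 to 58.4%). After shifts along the chromosomes these shares were 2.36%, 7.69% and 8.40%, so the observed overlap was 38.2, 10.1 and 6.93 times that of shifted peaks. Strong peaks overlapped more in the seedlings. Of the best-scoring 25% of H3K9ac peaks, 98.5% lay on H3K4me3 in Ae. tauschii and 89.3% in rye, against 57.7% and 40.6% of the lowest-scoring 25%. In the opposite direction, 44.7% of the wheat root H3K4me3 peaks carried H3K9ac, 58.0% in Ae. tauschii and 17.4% in rye.

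H3K4me3 and H3K27me3, marks of active and of repressed genes, also met more often than shifted peaks did. In Ae. tauschii 55.9% of the H3K4me3 peaks lay on H3K27me3 peaks (5.08 times the shifted share), in rye 23.7% (3.64 times), in wheat root 20.4% (9.70 times) and in wheat panicle 2.29% (23.6 times). In the panicle the H3K27me3 list was short, and 41.5% of its peaks lay on H3K4me3. The strength of these sites differed between the lists. In wheat root, 3.52% of the best-scoring 25% of H3K4me3 peaks lay on H3K27me3 but 38.9% of the lowest-scoring 25%. In Ae. tauschii the corresponding shares were 56.9% and 56.1%, and in rye 43.0% and 15.9%. H3K9ac joined the double-marked sites in the seedlings: peaks of H3K4me3 with both H3K9ac and H3K27me3 made up 30.0% of the Ae. tauschii list, with a median width of 1702 bp and a median fold enrichment of 19.8, and 9.69% of the rye list. In wheat root that class was 1.62%, and 3.96% of the H3K9ac peaks lay on H3K27me3, against 48.8% in Ae. tauschii and 45.9% in rye. These shares were 2.25, 4.48 and 6.83 times those of shifted peaks. Tissue differs here too, and the depth and calling of the wheat lists are unknown, so species is not separated from these. The seedling lists were called without a control library or local background. Whether sites with surplus reads in every library add to their shared sites was not tested here. Overlap of peak lists also does not show that the marks occur in the same cells. The widest shared stretches on assigned chromosomes were 17661 bp on rye chromosome 3 (32850597 to 32868257), 12996 bp on Ae. tauschii 6D (392748996 to 392761991) and 4416 bp on the first part of wheat 1D in root (342980 to 347395). The rye stretch also met an H3K9me2 peak of almost the same bounds.

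H3K9me2, which was mapped in rye alone, overlapped H3K4me3 more than the other marks. Of the rye H3K4me3 peaks, 51.0% lay on H3K9me2 peaks (50.9 to 51.1%), 3.82 times the shifted share of 13.3%. H3K9ac peaks did so in 28.2% of cases (1.89 times) and H3K27me3 peaks in 22.3% (1.24 times). The rye region on chromosome 3 from 32850597 to 32868257 was the widest H3K4me3 peak on assigned chromosomes and lay within 1 kb of the bounds of the widest H3K9me2 peak (32850746 to 32868227). Its fold enrichment was 197 for H3K4me3 and 170 for H3K9me2, and without a control library surplus reads at this site cannot be told from marks. The region carried peaks in all 4 lists, as did all 3 of the widest peaks of H3K4me3, H3K9me2 and H3K27me3 on those chromosomes. Such wide peaks meet long lists readily by their length alone, and this count was not set against shifted peaks.

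All 13 overlaps had an adjusted p of 0.0099, the smallest that 100 shifts can give, in the two-sided permutation test. The overlap of H3K9ac with H3K9me2 fell below that of shifted peaks (0.83 times) when only peaks of at least 500 bp were kept, and that of H3K27me3 with H3K9me2 did so with those peaks (0.81 times) and with the better-scoring 50% (0.85 times). Against local shifts, which keep the regional density, the ratios for H3K4me3 on H3K27me3 were 2.08 in Ae. tauschii and 5.50 in wheat root, those for H3K9ac on H3K27me3 2.31 in Ae. tauschii and 4.26 in rye, and that for rye H3K27me3 on H3K9me2 1.88, and with the better-scoring 50% the root ratio of H3K4me3 on H3K27me3 was 3.10.

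**Figure D1:**
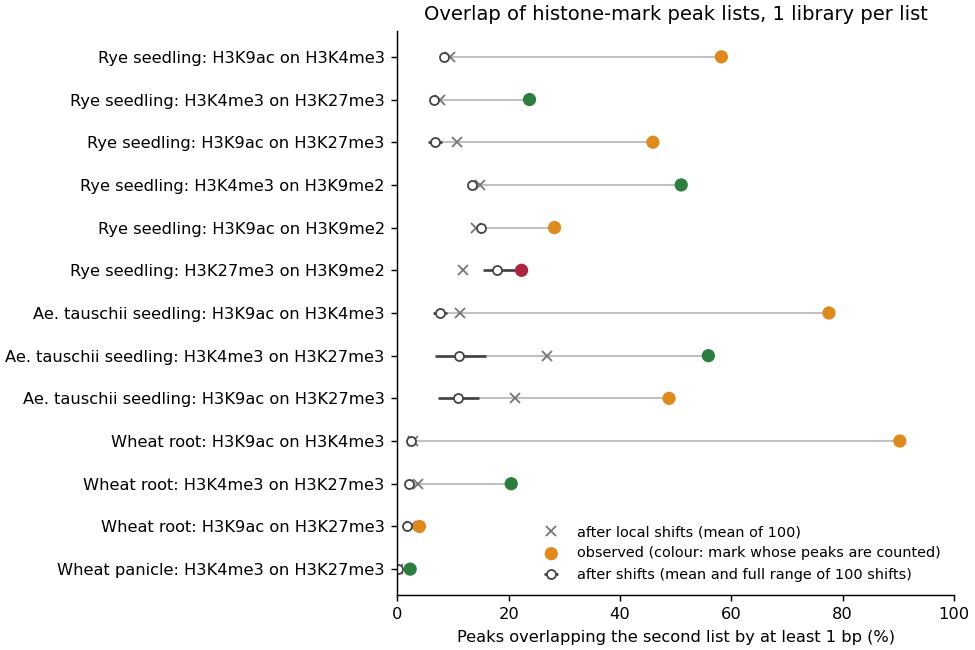
Share of the peaks of one mark that overlap a peak of another mark (percent, filled points, coloured by the mark counted), for 13 pairs of lists from 4 tissues, with the share after 100 circular shifts (open points, with their full range) and after local shifts (crosses, mean of 100). All observed shares lie above the range of the circular shifts, by the largest factor (38.2) for H3K9ac on H3K4me3 in wheat root.

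The second comparison asked where along the chromosomes the marks lay. H3K27me3 was gathered towards chromosome ends. The outer 20% at each end held 90.1% of the H3K27me3 peaks of wheat root, 88.1% in Ae. tauschii, 78.6% in wheat panicle and 71.5% in rye. Peaks per Mb there exceeded those of the central 20% by 31.1, 29.4, 5.81 and 6.80 times on average, on 21 of 21 wheat chromosomes in each tissue and on 7 of 7 chromosomes in each of the other species. The size of these ratios depended on the setting: the mean log2 ratio was 4.96 in wheat root (4.61 to 5.95 over the alternatives), 4.88 in Ae. tauschii (3.95 to 5.85), 2.54 in panicle (1.88 to 3.44) and 2.77 in rye (2.32 to 3.42). The active marks leaned the same way, less steeply. H3K4me3 was 3.65 times as dense at the ends in Ae. tauschii, 2.56 times in wheat root and 2.25 times in panicle, and H3K9ac 3.07 times in Ae. tauschii, 1.79 times in wheat root and 1.78 times in rye.

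Rye H3K4me3 and H3K9me2 departed from this. H3K4me3 was spread almost evenly in rye (1.07 times, denser at the ends on 4 of 7 chromosomes, adjusted p = 0.13 in the exact sign-flip permutation test). H3K9me2 was denser in the centre on 7 of 7 chromosomes, with an end-to-centre ratio of 0.66. In rye, H3K4me3 peaks without H3K9ac and H3K27me3, 68.6% of the list, had 31.7% of their number in the outer parts, whereas those with both marks had 66.6%. Peaks without these marks were also weaker and narrower, with a median fold enrichment of 4.62 and width of 303 bp, against 8.22 and 716 bp. In the sign-flip permutation tests the other 6 lists of rye and Ae. tauschii, H3K9me2 among them, had an adjusted p of 0.017 over 7 chromosomes each, and the 5 wheat lists one of 2.4e-05, from the smallest p that each test can give. With the better-scoring 50% of the rye H3K4me3 peaks the mean log2 ratio rose from 0.09 to 0.36 (adjusted p = 0.016, exact permutation test), and by covered bases it was 0.34.

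**Figure D2:**
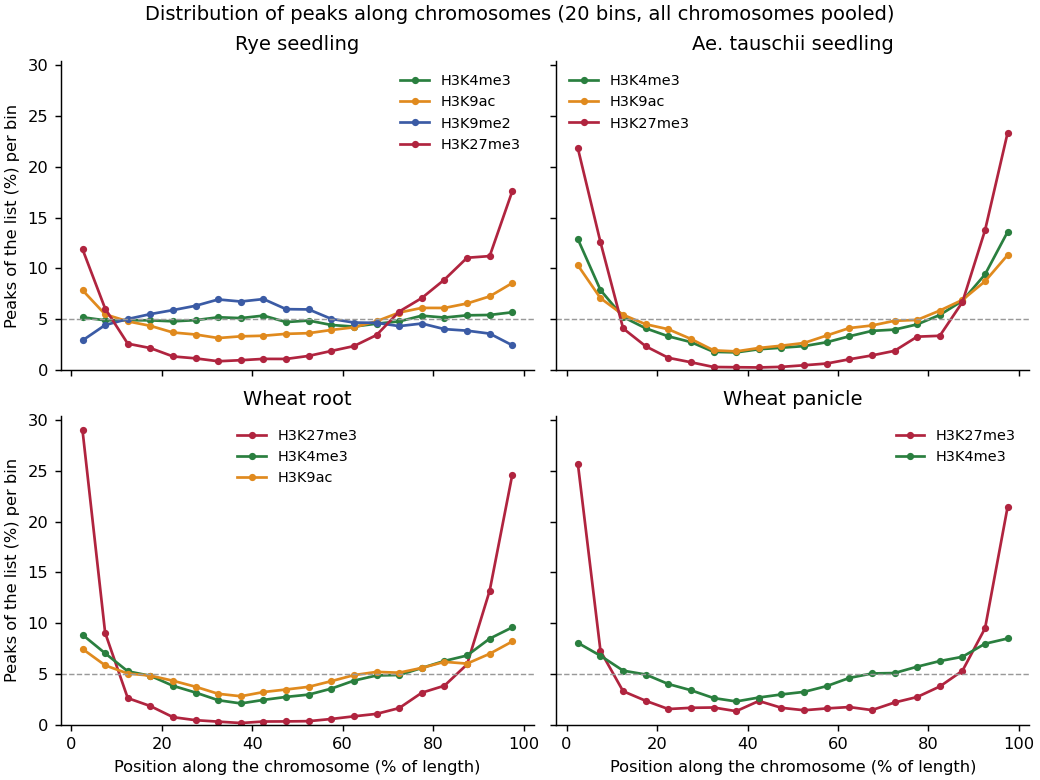
Percent of the peaks of each list (vertical axis) in 20 equal bins along the chromosome (horizontal axis, percent of length, all chromosomes of a species pooled), for 4 tissues, with colours for the marks and a dashed line at an even spread of 5%. The outermost bins hold 29.0% and 24.6% of the wheat root H3K27me3 peaks, and in rye the H3K9me2 profile is highest near the centre.

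The third comparison set wheat root against panicle. The H3K4me3 lists were close: 97.3% of the panicle peaks lay on root peaks (97.2 to 97.4%) and 83.4% of the root peaks on panicle peaks (83.2 to 83.6%). The H3K27me3 lists differed in length, in position along the chromosomes and in overlap. Of the panicle peaks 90.8% lay on root peaks (90.1 to 91.5%), but 5.09% of the root peaks on panicle peaks (4.97 to 5.22%). When the root list was cut to as many of its best-scoring peaks as the panicle list holds, which left 6669 of 113171, 31.8% of the panicle peaks lay on root peaks and 27.2% of the root peaks on panicle peaks. With the better-scoring 50% of each list, 82.5% of the panicle peaks lay on root peaks.

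Peaks of H3K4me3 found in 1 tissue list alone were weak, and a larger share of them than of the other H3K4me3 peaks lay on root H3K27me3. The 23058 root peaks without a panicle peak had a median score of 127.6, against 1232 for those with one, and a median width of 1036 bp against 1621 bp. Of the peaks without a panicle counterpart, 39.0% lay on root H3K27me3 (38.4 to 39.7%) and 8.31% on root H3K9ac, against 16.7% and 52.0% of the others. On panicle H3K27me3 lay 1.51% of them, against 1.98% of the others. Within the lowest-scoring 25% of root H3K4me3 peaks, 40.2% of those without a panicle counterpart lay on root H3K27me3 (39.5 to 40.9%) and 37.3% of those with one (36.6 to 38.1%). In the next 25% these shares were 36.1% (34.4 to 37.7%) and 27.5% (27.0 to 28.0%). The 3240 panicle peaks without a root peak had a median score of 80.6, and 35.0% lay on root H3K27me3, against 16.4% of the others. On panicle H3K27me3 lay 15.6% of them (14.4 to 16.9%), against 1.92% of the others. For root H3K27me3 the shares were 35.8% and 35.7% within the lowest-scoring 25% of panicle peaks, and 30.2% (25.8 to 34.9%) and 20.8% (20.4 to 21.3%) within the next 25%. At better scores few peaks were alone, and their share stayed higher: 17.9% against 10.97% in the second-best 25% in root, and 35.1% (26 of 74) against 7.59% in panicle. Among H3K4me3 peaks with no counterpart within 5 kb, the best-scoring in root was on the second part of 2A (161982654 to 161985737) and carried root H3K9ac, and the next was on the second part of 7D (139423707 to 139427275). The best-scoring in panicle was on the first part of 6D (290814150 to 290816837). The next panicle peaks, on the second part of 5A (117098068 to 117101201) and the first part of 6D (6273922 to 6276832), both lay on root H3K27me3 peaks. For H3K27me3, 90.3% of the root peaks had no panicle peak within 5 kb, and the best-scoring of them spanned 14737 bp on the second part of 7B (286478697 to 286493433). Peaks without a counterpart also lay more often in the outer 20% at each end, with 70.8% against 54.4% of the others in root and 63.4% against 54.3% in panicle. Those parts held 90.1% of the root H3K27me3 peaks, and position was not held constant in the shares above. With 1 library per tissue these shares were not tested, and a difference in depth, which is unknown, is not separated from tissue here.

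The fourth comparison was between the A, B and D subgenomes of wheat. The active marks were densest on D. Root H3K4me3 had 10.96 peaks per Mb on the D chromosomes, 9.63 on A and 9.22 on B. The D density exceeded A by 1.13 times and B by 1.19 times on average, in 7 of 7 homoeologous groups for both. Panicle H3K4me3 gave 1.13 and 1.19 times, and root H3K9ac 1.12 and 1.16 times, also in 7 of 7 groups. Each of these 6 contrasts had an adjusted p of 0.033 in the exact sign-flip permutation test, from the smallest p that 7 groups allow. Density of B against A did not pass the test for any mark, with an adjusted p of 0.12 for H3K4me3 in both tissues and for H3K9ac. With the better-scoring 50%, B fell below A for H3K4me3, with a mean log2 ratio of -0.19 in panicle and -0.15 in root (adjusted p = 0.026 for both, exact permutation test). The mean log2 D/A of H3K4me3 was then 0.07 in panicle and 0.11 in root, against 0.17 and 0.18 with all peaks. The D chromosomes are shorter, and per chromosome they held fewer H3K4me3 and H3K9ac peaks than A and B, with mean log2 ratios from -0.14 to -0.18.

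H3K27me3 passed no subgenome test in root. Its density there was 8.39 peaks per Mb on D, 7.91 on B and 7.91 on A, and none of the 3 contrasts passed the exact permutation test (adjusted p 0.70 to 1). The spread came from single chromosomes. Chromosome 4A had 10.4 root H3K27me3 peaks per Mb against 3.74 on 4B and 3.22 on 4D, and the log2 D/A ratio of group 4 was -1.69, while 6 of 7 groups had a higher density on D than on A. Without group 4 the mean log2 D/A rose from 0.03 to 0.31 (adjusted p = 0.052, exact permutation test, as for the active marks without that group) and B/A from -0.03 to 0.21 (adjusted p = 0.16). The last 60 Mb of 4A held 70.5 peaks per Mb, the highest of the 42 chromosome ends, against 18.7 at the end of 4B and 11.4 at the end of 4D. The first 60 Mb of 7B held 9.10 peaks per Mb, against 50.4 on 7A and 52.3 on 7D. Root H3K4me3 showed no such step at the end of 4A, with 15.4 peaks per Mb against 14.2 on 4B and 17.1 on 4D. In panicle, H3K27me3 was 0.72 times as dense on D as on B, lower in all 7 groups (adjusted p = 0.033, exact permutation test), with 0.41 peaks per Mb on D and 0.58 on B. This rests on the 6669 panicle peaks on chromosomes. The remaining 41.2% of that list lay on unplaced sequence and were assigned to no subgenome.

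**Figure D3:**
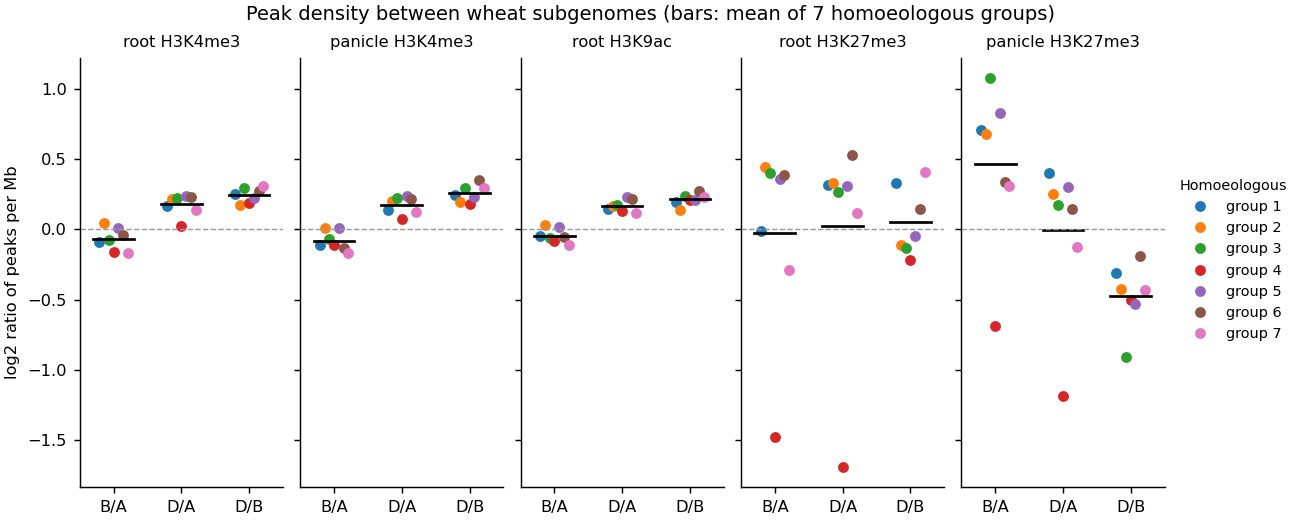
Log2 ratio of peaks per Mb between wheat subgenomes (vertical axis) for the 7 homoeologous chromosome groups (coloured points) and their mean (bars), in 5 wheat lists. D/A and D/B lie above 0 in 7 of 7 groups for H3K4me3 and H3K9ac, and group 4 stands apart for root H3K27me3, with a log2 D/A of -1.69.

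**Figure D4:**
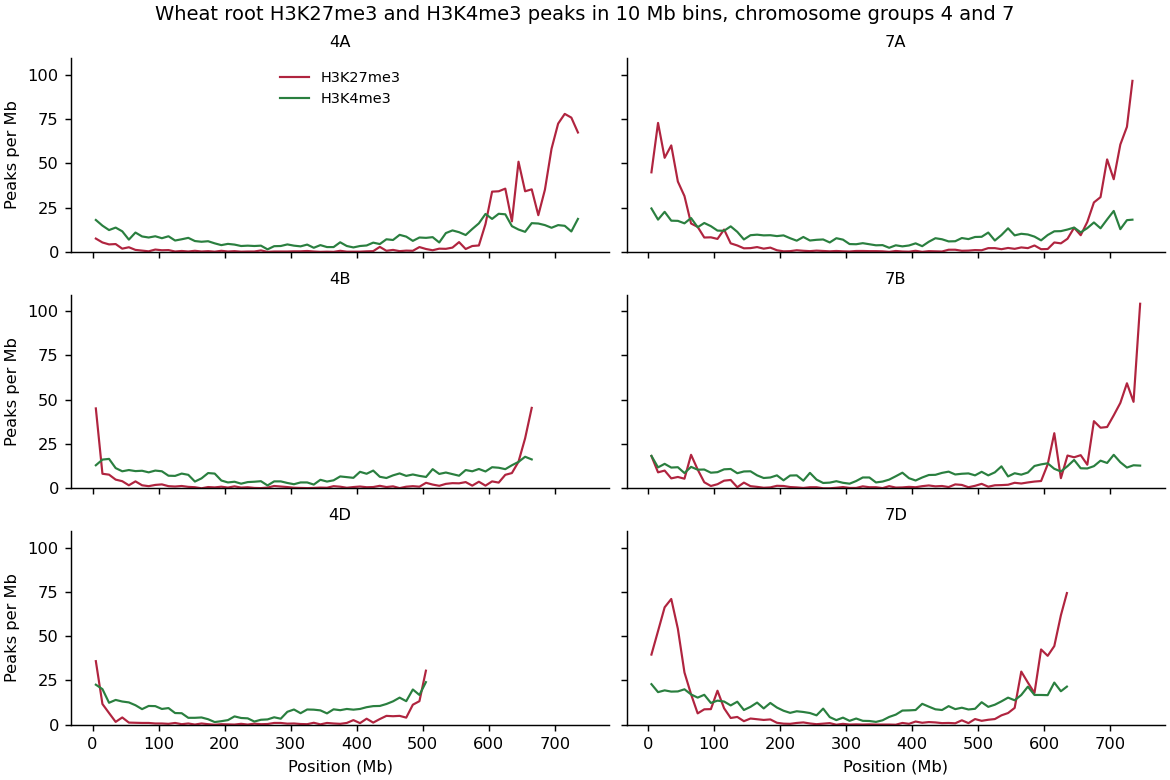
Peaks per Mb of wheat root H3K27me3 and H3K4me3 in bins of 10 Mb along the chromosomes of groups 4 and 7 (horizontal axis in Mb; final bins shorter than 5 Mb are not drawn). H3K27me3 rises over the end of 4A and over the start of 7A and 7D, where the first 60 Mb hold 50.4 and 52.3 peaks per Mb, and stays low at the start of 7B.

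The last comparison set rye against Ae. tauschii for the 3 marks mapped in both. Rye had 86.3 H3K4me3 peaks per Mb, with 73.0 to 92.0 on its 7 chromosomes, against 43.7 in Ae. tauschii (33.4 to 47.3), a ratio of 1.97. H3K9ac was sparser in rye, with 25.5 peaks per Mb (23.2 to 27.8) against 38.5 (31.5 to 42.0), a ratio of 0.66. H3K27me3 had 47.5 peaks per Mb in rye (31.2 to 67.2) and 60.01 in Ae. tauschii (27.2 to 90.0), a ratio of 0.79. Chromosomes differed most for H3K27me3. Within Ae. tauschii its density was 3.30 times as high on 7D as on 4D, whereas the highest and lowest chromosomes differed 1.42 times for H3K4me3 and 1.34 times for H3K9ac. In rye, chromosome 6 exceeded chromosome 2 by 2.16 times for H3K27me3.

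The direction of 2 of these ratios depended on what was counted. By covered bases, H3K4me3 was lower in rye (0.71 times, with 3.93% of the chromosomes covered against 5.50%), although after peaks within 1 kb were merged it was 3.17 times as dense. H3K9ac stayed lower, at 0.42 times by covered bases and 0.95 times after merging. H3K27me3 turned higher in rye after merging (1.46 times) or a fold enrichment of at least 4 was asked (1.16 times). Ae. tauschii libraries were 5.37 to 6.31 times as deep per kb, and with 1 library per species these ratios were not tested.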

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

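The tests of differences between lists in the next paragraph and those on peaks outside the assigned chromosomes were chosen after the main results had been seen, except that the bounds for the overlaps of unplaced peaks were written before these were computed.

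The same contrast gave different values in different lists. The end-to-centre log2 ratio of peaks per Mb was lower in rye than in Ae. tauschii for H3K4me3 (0.09 against 1.87, difference -1.78, adjusted p = 0.0021), H3K9ac (0.83 against 1.62, difference -0.79, adjusted p = 0.037) and H3K27me3 (2.77 against 4.88, difference -2.11, adjusted p = 0.0096), in exact permutation tests over 7 chromosomes of each species. Between wheat root and panicle it differed by 0.19 for H3K4me3 (1.35 in root, 1.17 in panicle) and by 2.42 for H3K27me3 (4.96 in root, 2.54 in panicle), both with an adjusted p of 5.5e-05 from the smallest p that 100000 sign flips over 21 chromosomes can give. The subgenome ratios of H3K27me3 differed between root and panicle for B/A (root minus panicle -0.49, adjusted p = 0.049) and D/B (0.53, adjusted p = 0.034) in exact permutation tests over 7 groups. Peaks on unplaced sequence, 41.2% of the panicle list, are not in these ratios. The 11 tests formed 1 family, and they compare single libraries, so species, tissue and library are not separated.

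Peaks on unplaced sequence were in no main comparison. They made up 1.85% of rye H3K4me3, 3.67% of H3K9ac, 1.41% of H3K9me2 and 3.79% of H3K27me3 peaks, 2.08% of Ae. tauschii H3K4me3, 2.24% of H3K9ac and 6.93% of H3K27me3 peaks, and 1.71% of wheat root H3K4me3, 1.47% of H3K9ac and 8.32% of H3K27me3 peaks. In wheat panicle they were 1.90% of H3K4me3 but 41.2% of H3K27me3 peaks, although unplaced sequence makes up 3.31% of the wheat length spanned by peaks.

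The panicle H3K27me3 surplus on unplaced sequence comprised 4680 peaks, with a median score of 130 against 83.1 for its peaks on chromosomes. Of these, 93.8% lay on root H3K27me3 peaks, against 5.33% after shifts, so most are in a second H3K27me3 list too. Sites with surplus reads in every library, such as collapsed repeats, remain open: 22.4% of the unplaced peaks lay on root H3K9ac or panicle H3K4me3 peaks, between the bound of 50% that would have favoured them and that of 10% that would have spoken against them. Relative to shifted peaks, the unplaced peaks met root H3K9ac 16.9 times, panicle H3K4me3 19.96 times, root H3K4me3 13.8 times and root H3K27me3 17.6 times as often. The last ratio is near its ceiling, since 93.8% of the peaks already overlapped, so these ratios cannot rank the lists. By share, 6.92% lay on root H3K9ac, 20.9% on panicle H3K4me3 and 16.8% on root H3K4me3. Why the panicle list holds these sites and lacks most root sites on chromosomes is open, and a biological difference between the tissues was not tested.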

How the results depend on the processing

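Of 78 alternative values of the 13 overlaps, 73 kept their direction and their side of the threshold. For rye H3K9ac on H3K9me2 the ratio to shifted peaks was 1.02 with the better-scoring 50% of each list, no longer past the test, and 0.83 with peaks of at least 500 bp. For rye H3K27me3 on H3K9me2 it was 0.85 and 0.81 under these settings and 1.06, not past the test, without peaks found in all lists. The cause was not tested, except that the last setting removes overlapping peaks by construction and so says nothing on stability. It also took Ae. tauschii H3K9ac on H3K27me3 to 1.15 (share 7.85%) and H3K4me3 on H3K27me3 to 2.47 (share 16.1%). Over the other 5 settings the ratios in rye ranged from 6.10 to 15.3 for H3K9ac on H3K4me3, 3.09 to 5.52 for H3K4me3 on H3K27me3, 4.26 to 9.19 for H3K9ac on H3K27me3, 3.12 to 5.45 for H3K4me3 on H3K9me2, and up to 3.47 and 2.15 for H3K9ac and H3K27me3 on H3K9me2. In Ae. tauschii they ranged from 6.94 to 13.7, 2.08 to 6.31 and 2.31 to 5.24 for the first 3 of these pairs, in wheat root from 31.3 to 57.9, 3.10 to 15.4 and 1.53 to 2.86, and in panicle from 16.4 to 58.4 for H3K4me3 on H3K27me3. The settings of local shifts, peaks found in all lists, unplaced sequence and peaks per chromosome were chosen after seeing the data. Of 48 alternatives on position, 46 kept their call, and rye H3K4me3 passed the test with log2 ratios of 0.36 (better-scoring 50%) and 0.34 (covered bases). The log2 ratio of H3K27me3 stayed past the test but ranged from 4.61 to 5.95 in wheat root, 3.95 to 5.85 in Ae. tauschii, 2.32 to 3.42 in rye and 1.88 to 3.44 in panicle.

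Shares between root and panicle moved beyond their interval in 20 of 24 cases. Panicle H3K4me3 on root was 92.1% with the better-scoring 50%, 93.1% with equal numbers, 97.2% with an overlap of 50% of the peak, 97.5% after merging and 97.1% with unplaced sequence. Root H3K4me3 on panicle was 80.02%, 91.3%, 80.6% and 84.8% under the first 4 of these. Panicle H3K27me3 on root was 82.5%, 31.8% and 89.9% under the first 3, 92.0% with unplaced sequence and 89.2% without peaks found in all lists. Root H3K27me3 on panicle was 4.58%, 27.2%, 3.04% and 7.09% under the first 4, 7.80% with unplaced sequence and 4.50% without peaks found in all lists. Equal numbers take the top of the longer list alone, which by construction removes its weaker matches.

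Of 165 alternatives on subgenomes, 108 kept their call. With the better-scoring 50%, B fell below A for H3K4me3, with log2 ratios of -0.19 in panicle and -0.15 in root past the test. In that setting D/A of H3K4me3 shrank from 0.17 to 0.07 in panicle and from 0.18 to 0.11 in root, still past the test. For root H3K9ac it was 0.19, against 0.17 with all peaks. D/B was 0.26 for panicle H3K4me3, 0.26 for root H3K4me3 and 0.21 for root H3K9ac. Leaving out 1 homoeologous group left no contrast past the adjusted threshold, since 6 groups allow no p below 0.031 and the adjusted p was 0.052 to 0.067. The direction held: D/A ranged from 0.16 to 0.19 for panicle H3K4me3, 0.17 to 0.20 for root H3K4me3 and 0.16 to 0.18 for root H3K9ac, and D/B from 0.24 to 0.27, 0.24 to 0.26 and 0.20 to 0.23. For panicle H3K27me3 D/B ranged from -0.52 to -0.40. For root H3K27me3, D/A ranged from -0.06 to 0.31 and B/A from -0.11 to 0.21, both highest without group 4 (adjusted p 0.052 and 0.16). Counted per chromosome, D/A turned to -0.15 (panicle H3K4me3), -0.15 (root H3K4me3) and -0.16 (root H3K9ac), each past the test, and D/B to -0.14, -0.15 and -0.18, of which H3K9ac passed. The D chromosomes are shorter, so the sign of these contrasts depends on whether peak numbers are divided by length.

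Halving both lists cannot change the ratio of rye to Ae. tauschii, so the better-scoring 50% tests nothing there. With a fold enrichment of at least 4 it was 2.70 for H3K4me3, 0.97 for H3K9ac and 1.16 for H3K27me3, after merging 3.17, 0.95 and 1.46, and by covered bases 0.71, 0.42 and 0.52. Depth, 5.37 to 6.31 times greater per kb in Ae. tauschii, limits this comparison, and the unknown depth of the wheat lists limits that of root and panicle. Not run, for want of a genome or annotation of the same build, were shares near genes, marked genes, repeat content, peaks per annotated gene and other chromosome lengths, with their alternatives. No paired analysis was possible because no groups share replicates.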

Other observations

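Among the tests of this part, the correlations, the moved segment, the sites in all 4 rye lists and the weak calls were chosen after related values had been seen.

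The density of H3K27me3 per chromosome was alike in Ae. tauschii seedlings and on the D chromosomes of wheat root. Over the 7 D chromosomes Pearson's r was 0.98 (exact permutation p = 0.0012, adjusted 0.011) and Spearman's rho 0.89 (p = 0.012, adjusted 0.036), and r was 0.86 without the chromosomes 4D and 7D, which lay farthest from the median. Among 9 such relations, the rho of Ae. tauschii H3K27me3 with the wheat A chromosomes was 0.25 and with the B chromosomes 0.96 (adjusted p 0.59 and 0.013). By Pearson's r the relation with B was 0.84 and did not pass (exact permutation test, adjusted p = 0.056). Without the chromosomes of groups 4 and 7, r was 0.76 with A, up from 0.17, and 0.92 with B, so the low value with A rests on those 2 groups and the relation is not particular to D. For H3K4me3 the r with the D chromosomes was 0.92 (exact permutation p = 0.028, adjusted 0.056) and the rho 0.86 (adjusted 0.036). With the A chromosomes H3K4me3 had an r of 0.79 (adjusted 0.013) and a rho of 0.86 (adjusted 0.036). With B they were 0.72 (adjusted 0.079) and 0.71 (adjusted 0.11), in the same permutation tests. H3K9ac had a rho of 0.68 with D (adjusted 0.12), 0.86 with A (adjusted 0.036) and 0.96 with B (adjusted 0.013). Its r was 0.79 with D (adjusted 0.067), 0.70 with A and 0.71 with B (adjusted 0.056 for both), again in those permutation tests. Chromosome 4D was lowest and 7D highest for H3K27me3 in both lists, with 27.2 and 90.0 peaks per Mb in Ae. tauschii and 3.22 and 12.2 in wheat root. In rye, H3K27me3 was dense at the far end of several chromosomes. From 1000 Mb on, chromosomes 4, 7 and 6 held 263, 242 and 237 peaks per Mb and chromosome 3 held 96.0. Chromosome 2 held 70.4 from 1000 to 1100 Mb and 95.3 beyond. Chromosomes 1 and 5 held 113 each from 900 Mb on. The last window of each chromosome is shorter than 100 Mb and differs in length, so these densities are not like for like. Chromosome 3 was denser in its first 100 Mb, with 159 peaks per Mb. From 800 to 900 Mb the densities were 215 on chromosome 4, 204 on 6, 89.3 on 1, 64.2 on 5, 43.0 on 7, 23.3 on 2 and 20.2 on 3. This window lies at different distances from the chromosome ends.

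For the dense H3K27me3 at the end of 4A and its low density at the start of 7B, a chromosome segment that moved from 7B to 4A is a candidate explanation, and such a rearrangement is known in wheat. The last 60 Mb of 4A held 1.37 times the mean density of the first 60 Mb of 7A and 7D, a value that would have spoken against the segment below 0.5, but the explanation was drawn from these same densities, so they are no independent test. A greater density of peaks of any mark in the last 60 Mb of 4A is argued against, since the ratio of 4A to the mean of 4B and 4D was 4.75 times as large for H3K27me3 as for H3K4me3 in root. The panicle H3K27me3 list, with far fewer peaks, had 3.93 peaks per Mb at the end of 4A, 0.83 at the end of 4B and 0.72 at the start of 7B, but with 1.97 at the start of 7A and 1.75 at that of 7D its 4A end was 2.12 times their mean, above the range that a moved segment was expected to give. Read mapping between homoeologous copies was not tested.

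Of the rye H3K4me3 peaks on H3K9me2, surplus reads that every library carries may account for a part, since no control library was used. These peaks lay on H3K27me3 2.49 times as often as after local shifts (13.2% against 5.32%), although H3K4me3 peaks off H3K9me2 did so 3.41 times as often. Of the H3K4me3 peaks on H3K9me2, 4.14% lay on both other marks, so sites called in all 4 lists were a small part. List lengths allowed little else, since 60647 H3K4me3 peaks lay on both other marks, against 319038 on H3K9me2. This value therefore does not speak against sites with surplus reads that the H3K9ac list missed. Peaks that also carry H3K9ac could not be the main part of the overlap whatever their share, since 108711 H3K4me3 peaks carried H3K9ac, against 319038 on H3K9me2. H3K4me3 peaks with H3K9ac lay on H3K9me2 0.49 times as often as those without (27.3% against 56.0%). Position was not held constant here, and H3K9ac leaned towards the chromosome ends but H3K9me2 towards the centre. Whether weak calls carry most of the overlap could not be decided from the best-scoring 10% of H3K4me3 peaks. These lay on H3K9me2 1.49 times as often as after local shifts (25.8% against 17.3%, above all 100 shifts). Without a control library they may include sites with surplus reads. Their ratio was also less than the 3.45 times (51.0%) of all H3K4me3 peaks, so the strongest peaks overlapped less. From the best-scoring to the lowest-scoring 25% of H3K4me3 peaks, the shares on H3K9me2 were 46.5%, 56.2%, 52.6% and 48.6%. The share therefore did not rise steadily towards weaker peaks. Whether a common set of repeats carries both marks, or antibody cross-reaction adds reads, was not tested.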
